A study of Mus musculus with 19 samples.

How the data were processed

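RNA was measured by bulk sequencing of the hippocampus of 19 mice labelled as female, taken after perfusion with buffered saline. RNA was isolated with the NucleoSpin RNA kit and libraries were made with the TruSeq RNA Sample Prep Kit, 1 per animal. The submitters' processing notes name STAR 2.6, HTSeq, edgeR and the mm10 build without giving their roles or order, and do not state the annotation release, the gene filter or how strand was used in counting. Groups were taken from the labels: NZB/W-F1 at 3 months (4 animals) and 6 months (5), and C57BL/6 at 3 months (5) and 6 months (5). NZB/W-F1 and C57BL/6 animals carry separate ranges of sample numbers, as do the ages within each strain, and the labels give no batch, litter or pairing. Neither strain nor age can thus be told apart from any difference in handling between these groups.

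The deposited table gives 1 value per gene and library for 15303 genes. The signal values, as deposited by the authors, behave as read counts scaled to library size with the normalization factors of edgeR, and levels on this scale, which differs from plain CPM by those factors, are written as CPM. Every value was a whole multiple of a single step per column, so that 100% of the values gave whole reads within a tolerance of 0.01 reads, and column totals ran from 969213 to 1022531. The plan written before the data were examined had assumed plain CPM, for which 2 column totals passed the upper limit. The recovered reads gave depths of 12.95M to 28.78M reads in genes. At those depths 3 reads, the most that a count of 0 allows at 95% confidence, came to at most 0.153 and 0.178 CPM in NZB/W-F1 at 3 and 6 months and 0.215 and 0.231 CPM in C57BL/6, per library. Such floors cover counting error only, since reads carry no molecular identifiers. Of the gene symbols 22 had been turned into dates and were restored, 15295 identifiers were matched to GENCODE M21 (GRCm38, which is mm10) by name without version and 14491 with it, and 4 symbols stood for more than 1 gene.

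Genes with at least 1 CPM in at least 4 libraries were tested, 15298 genes, and 5 were left out. Values were taken to log2(CPM + 1), and a fold on that scale is smaller than the ratio of the CPM for low genes. One limma model (lmFit and eBayes with a trend, two-sided) held the 4 group means of all 19 libraries. Its 5 contrasts were NZB/W-F1 minus C57BL/6 at 3 months, the same at 6 months, 6 minus 3 months in NZB/W-F1, 6 minus 3 months in C57BL/6, and the difference between these age changes (the interaction). Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. Agreement of the strain differences was described by Pearson's r across genes, the share of genes with the same sign and the number called at both ages. The tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9 and blastn 2.17.0.

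Before the data were examined, 38 gene lists, the contrasts, the tests, the alternatives and the rule for named genes had been fixed. The lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 36 lists with at least 4 genes tested. Calls from it were set beside camera with an estimated correlation and fry. Of all calls, that of the oligodendrocyte precursors with age in NZB/W-F1 alone held with an estimated correlation. The lists covered homeostatic and activated microglia, interferon-stimulated genes, MHC class I and class II presentation, complement, cytokines with the inflammasome, neural stem and progenitor cells, neuroblasts, apoptosis with p53 targets, astrocytes, reactive astrocytes, myelin, oligodendrocyte precursors, endothelium, endothelial activation, pericytes, choroid plexus, meninges, blood cells, B and plasma cells, T and NK cells, border-associated macrophages, excitatory synapse, GABAergic interneurons, immediate early genes, dentate gyrus, CA1, CA3, thalamus, striatum, neocortex, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, lupus susceptibility genes, glucocorticoid response, and heat shock with the unfolded protein response. B and plasma cells and T and NK cells had 2 genes each in the table, below the minimum, and were not tested.

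Camera called 9 of the lists in no comparison. With age in NZB/W-F1 their median log2 fold changes and adjusted p were -0.01 and 0.201 for neural stem and progenitor cells, 0.04 and 0.27 for apoptosis, 0.01 and 0.423 for astrocytes, 0.07 and 0.389 for endothelium, 0.20 and 0.174 for endothelial activation, and -0.01 and 0.201 for pericytes. For regions other than the thalamus, the median was below 0.01 in size for CA3, striatum and neocortex, with adjusted p of 0.544, 0.891 and 0.493. At 6 months between strains the endothelium had a median of 0.14 (adjusted p = 0.0963) and CA3 of 0.30 (0.0963). Of 5 genes of endothelial activation limma called 3 there and 0 with age in NZB/W-F1. Its mean z-score per library was 0.500 ± 0.329 in NZB/W-F1 and -0.255 ± 0.345 in C57BL/6 at 6 months. The exact two-sided permutation p was 0.0159 there and 0.0159 with age in NZB/W-F1. After adjustment over the lists these were 0.0952 and 0.0816.

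The rule for named genes took, per comparison, genes with adjusted p under 0.05, a mean of at least 1 CPM and no overlap between the libraries of the groups compared. Of those it named the 5 with the highest and the 5 with the lowest log2 fold change whose symbols are not predicted-gene names, the 2 members with the smallest adjusted p from each of 10 priority lists, and 1 from every other list that camera called. Il6, Il18, Il1b, Tnf, Aif1, Dcx, Gfap, Ifi202b, C4b and Ttr were named whatever their values. The rule gave 67 genes in 124 entries, and the other list members and copies given as examples were chosen after their values were seen. Per library, a list score was the mean z-score of its genes over the 19 libraries, compared by an exact two-sided permutation test, adjusted over the lists.

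Processed pseudogenes were searched with blastn against all protein-coding transcripts of GENCODE M21, and the best match was kept without a minimum of aligned bases or identity. Named genes were searched against the transcripts of all genes tested, with at least 300 aligned bases and 95% identity. Of the 67 named genes 16 had such a copy (C4a, C4b, Eno1b, Ftx, H2-DMa, H2-T22, Hba-a2, Hbb-bt, Ly6c2, Ndufs1, Ndufs5, Pcna, Rbm3, Rpl29, Rplp0 and Rps3a3), and for these and for genes with an antisense partner it remains uncertain to which gene shared reads were assigned. The alternatives tried were other filters, pseudocounts of 0.25 and 4, other scalings, fits on the compared groups alone, array weights, robust moderation, edgeR and DESeq2 on the recovered reads, a minimum log2 fold change of 0.5, and leaving out each library. Alternatives added after the data were seen left out libraries 39 and 40 of C57BL/6 at 3 months, took the trend of expression with transcript length (over 9981 genes of at least 10 CPM) or the globin Hbb-bs as a covariate, or left out pseudogenes and pancreatic genes. For each count, 100 splits of the libraries into groups of the same sizes were drawn. The code was tested on simulated data with changes planted in the age contrast of NZB/W-F1, over 15128 genes. There limma recovered 30 of 67 genes changed 1.5-fold (44.8%), 58 of 66 changed 2-fold (87.9%) and 64 of 65 changed 4-fold (98.5%), with 6 false calls. On the same data edgeR gave 7 false calls and DESeq2 25. In the age contrast of C57BL/6, where nothing was planted, limma and edgeR gave 0 and DESeq2 3. Genes were drawn independently of each other, so the simulation holds no structure shared between genes of a library.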

Results

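Bulk RNA of the hippocampus was sequenced from 19 mice labelled as female, 1 library per animal. NZB/W-F1 mice, hybrids that develop a lupus-like disease without treatment, were taken at 3 months, before kidney disease (n = 4), and at 6 months, when proteinuria had shown nephritis (n = 5). C57BL/6 mice of 3 months (n = 5) and 6 months (n = 5) served as controls of the same ages. The libraries held 19.54M to 25.08M reads in genes for NZB/W-F1 at 3 months and 16.47M to 28.78M at 6 months. Those of C57BL/6 held 14.29M to 18.41M at 3 months and 12.95M to 17.7M at 6 months. Library 33 of C57BL/6 at 6 months held 0.29 CPM of Xist, against 224.3 to 704.6 in the other 18, which goes against its female label. Levels are given in CPM, reads scaled to a common library size, as mean ± SD over the libraries of a group, and log2 fold changes on the log2(CPM + 1) scale ± SE from limma, with positive values for NZB/W-F1 over C57BL/6 or for 6 over 3 months.

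The comparison at 3 months asked how the lupus-prone hippocampus differed from that of controls before nephritis. Microglial genes differed in both directions. Fcrls, a receptor of homeostatic microglia, stood at 6.73 ± 1.46 CPM in NZB/W-F1 (n = 4) and 36.4 ± 6.84 in C57BL/6 (n = 5), a log2 fold change of -2.28 ± 0.17 (limma adjusted p = 4.72e-09). Olfml3, another homeostatic gene, was lower (-0.88 ± 0.08), whereas Lpl, a lipase of lipid-handling microglia, was higher by 1.29 ± 0.16. Among 15 homeostatic microglial genes 3 were higher and 3 lower, and the list as a whole did not pass, with a median of 0.14, a mean of -0.10 and an adjusted p of 0.811 from limma's camera. The 18 activated microglial genes, Lpl among them, had 1 higher and 3 lower, with Gpnmb among the lower. That list had 13 genes below 0 and a median of -0.27, and camera did not call it (adjusted p = 0.123). Among the precursors of oligodendrocytes, 4 of 10 genes were higher and 5 when adjusted over the list alone, and the list passed camera with a median of 0.34 and an adjusted p of 0.0359. It lost its call without library 5 or 7 of NZB/W-F1 (median 0.32 and 0.30, adjusted p = 0.0614 and 0.0686). Gpr17, which marks precursors committed to differentiate, was higher by 0.71 ± 0.14, Vcan by 0.61 ± 0.15 and Olig2 by 0.38 ± 0.10.

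Of 17 genes of MHC class I presentation, 4 were lower over all genes tested and 4 adjusted over the list alone, with a median of -0.21 and a camera adjusted p of 0.0359. They were H2-T22 (-1.46 ± 0.12), H2-T23 (-1.05 ± 0.30), H2-K1 (-0.91 ± 0.29) and B2m, the light chain of MHC class I (-0.57 ± 0.17). H2-T22 shares 96.48% of 1703 aligned bases with H2-T10, which went the other way, higher by 1.12 ± 0.16 (limma adjusted p = 3.97e-05). Whether variants of NZB/W-F1 against the C57BL/6 reference changed the reads assigned to H2 genes was not tested. Strain differences of single H2 genes may therefore reflect read assignment as well as expression. The list lost its call without library 5 or 7 of NZB/W-F1 or 39 of C57BL/6 (median -0.25, -0.13 and -0.12, highest adjusted p = 0.153), and its median was -0.35 without library 36 or 38 of C57BL/6. The 30 interferon-stimulated genes had a median of -0.32, with 26 below 0 and a camera adjusted p of 0.0394. No single one passed limma over all genes or adjusted over the list alone, 5 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 3. That list lost its call without library 5 or 7 of NZB/W-F1 or 38 or 39 of C57BL/6 (median -0.30, -0.28, -0.29 and -0.22, highest adjusted p = 0.123). Under settings chosen after the data were seen, both calls were lost without libraries 39 and 40 of C57BL/6 together (median -0.14 for MHC class I and -0.18 for interferon). That of MHC class I was also lost with the trend of expression with transcript length, a sign of RNA quality, as a covariate (median -0.14). Pycard, the adaptor of the inflammasome, was lower (-1.23 ± 0.14) and the alarmin Il33 (-0.87 ± 0.15). With these, limma called 4 of the 16 genes of the list of cytokines with the inflammasome, which camera did not call. In the complement list C4a was higher by 0.84 ± 0.14, while C4b, which shares 95.96% of 5378 aligned bases with it, had a log2 fold change of -0.48 ± 0.16 (limma adjusted p = 0.0621), and C1qb was lower (-0.83 ± 0.17).

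Of the 16 genes of the heat shock and unfolded protein response, 5 were higher and 2 lower at 3 months, against 8 and 2 adjusted over the list alone, with a median of 0.30 and a camera adjusted p of 0.0394. Without library 5 or 7 of NZB/W-F1 or 36, 37 or 38 of C57BL/6 the list lost its call (median from 0.24 to 0.29, highest adjusted p = 0.123). Higher members included Hspa5 by 0.73 ± 0.15, Pdia4 by 0.52 ± 0.15 and Calr by 0.48 ± 0.12. The 2 lower ones were the stress-induced factor Atf4 (-0.63 ± 0.11) and Hspa8 (-0.31 ± 0.08). Immediate early genes, which follow neuronal activity, had a median of -0.51, with 1 of 14 higher and 2 lower, and 1 and 6 adjusted over the list alone. Egr1 was lower (-0.64 ± 0.14) and Ier2 (-0.61 ± 0.19), whereas Fosl2 was higher by 0.43 ± 0.13, and the camera adjusted p was 0.0394. Without library 5 or 9 of NZB/W-F1 or 36, 37, 38 or 39 of C57BL/6 this call was lost (median from -0.54 to -0.41, highest adjusted p = 0.124). All 31 ribosomal protein genes lay below 0 with a median of -0.24 and a camera adjusted p of 0.000896, 2 of them called and 4 adjusted over the list alone. Without library 39 of C57BL/6 the median was -0.06 and the call was lost (adjusted p = 0.121). Nuclear-encoded genes of oxidative phosphorylation had a median of -0.19 over 23 genes, of which 1, Ndufs1, was called, and no member passed when adjusted over the list alone (unadjusted p under 0.05 for 4, edgeR 0 and DESeq2 2 over all genes). The camera call of that list was lost without library 5 or 7 of NZB/W-F1 (adjusted p = 0.0702 and 0.0686) or 39 of C57BL/6 (median -0.07, adjusted p = 0.478), and its median turned to 0.02 without libraries 39 and 40 together and was -0.04 with the length trend as a covariate. The ribosomal median was 0.001 and -0.04 under these settings, both chosen after the data were seen, and neither list was called. Blood cell genes were lower, 3 of 5 both over all genes and adjusted over the list alone, with a camera adjusted p of 0.002, and that list kept its call without each library. Of its genes edgeR called 1 and DESeq2 1, and Hbb-bs stood at 24.5 and 13.6 CPM in libraries 5 and 7 of NZB/W-F1, at 0.12 and 0.0423 in libraries 8 and 9, and from 13.8 to 45 in C57BL/6. Its member Hba-a2 was at 0.0511 CPM in library 7 and at 0 in libraries 5, 8 and 9 of NZB/W-F1. For Hba-a1, a copy of 99.81% identity, the log2 fold change was -1.28 (limma adjusted p = 0.198). With an estimated correlation each of the 8 lists lost its call, with adjusted p = 0.492 with an estimated correlation for the oligodendrocyte precursors and 0.903 for the other 7.

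Over the 15298 genes tested, limma called 914 higher and 776 lower in NZB/W-F1 at 3 months, and 187 and 85 of these by more than 2-fold. Among the most extreme values were those of genes with near-identical copies and of pancreatic enzymes. Eno1b (ENSMUSG00000059040.4, chromosome 18, 48045335 to 48048412, mm10), a copy of the enolase gene Eno1, stood at 56.6 ± 6.34 CPM in NZB/W-F1 and 0.253 ± 0.0788 in C57BL/6, a log2 fold change of 5.52 ± 0.10 (limma adjusted p = 7.62e-19). Eno1b and Eno1 share 99.5% of 1736 aligned bases, and Eno1 was lower in NZB/W-F1, at 276.4 CPM against 522. Ndufs5 (ENSMUSG00000028648.13, chromosome 4, 123712710 to 123718202), a subunit of complex I, was at 0.839 ± 0.123 CPM against 27.5 ± 10.1 (-3.90 ± 0.17). Its copy BC002163 on chromosome 16 was at 22.7 ± 1.5 against 1.11 CPM. Rps3a3 was higher by 4.69 ± 0.10, and Pttg1 (-3.67 ± 0.16), Rpl29 (-2.70 ± 0.17) and Etnppl (-2.76 ± 0.39) were lower. Of these, Rps3a3 and Rpl29 also had a copy of at least 95% identity among the genes tested, whereas none was found for Pttg1 and Etnppl. The pancreatic proteases Ctrb1 and Cpa1 were at 23.3 ± 5.59 and 12.2 ± 3.09 CPM and at 0 in every C57BL/6 library of 3 months, where 3 reads came to at most 0.215 CPM, so that Ctrb1 was at least 108-fold higher and Cpa1 at least 56.8-fold. Of the 30 genes named for this comparison 25 kept their call without each of the 19 libraries. The highest adjusted p for the other 5 was 0.0798 for H2-T23, 0.106 for H2-DMb1 (-0.84 ± 0.25), 0.0503 for Mcm2 (-0.48 ± 0.12), 0.0717 for Pcna (-0.27 ± 0.07) and 0.175 for Ndufs1 (-0.16 ± 0.05).

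**Figure D1:**
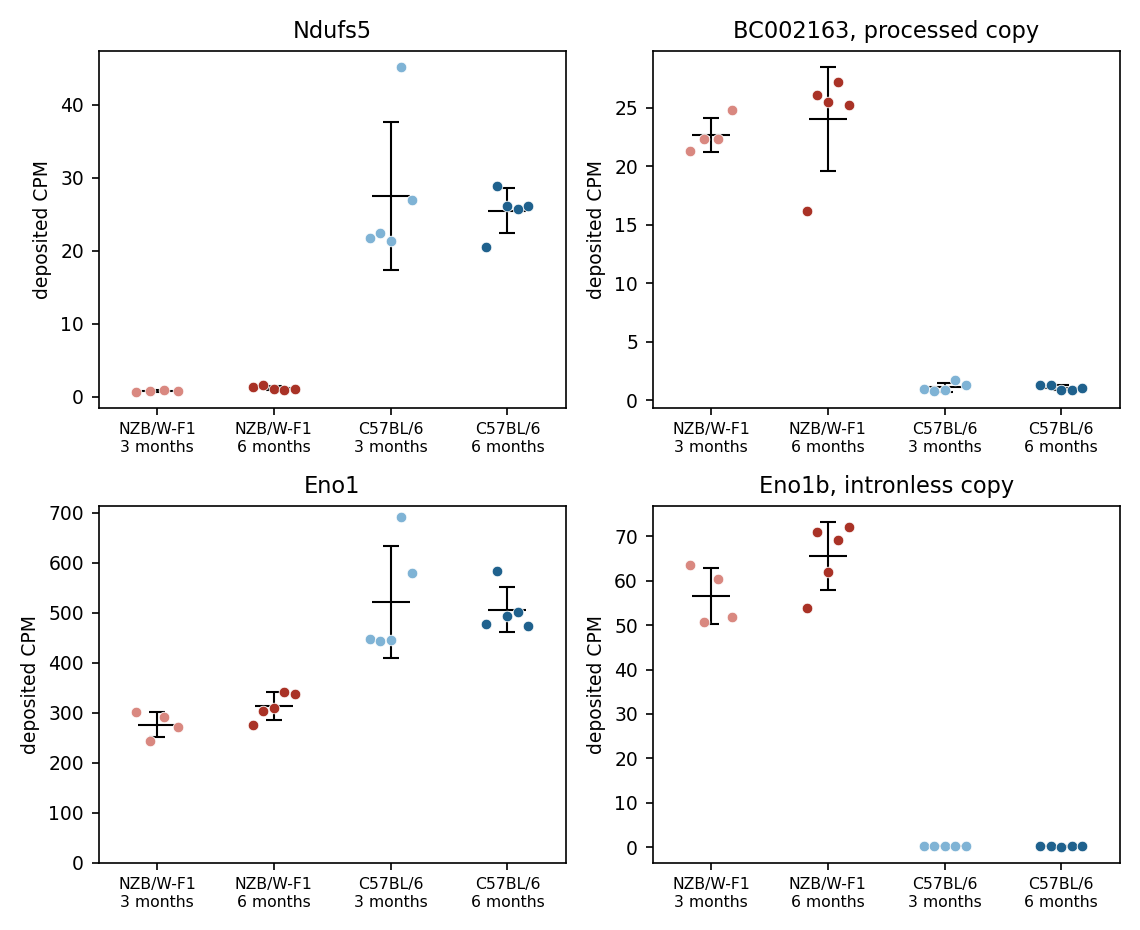
CPM of each library (points, linear axis from 0) with mean and SD (bars) by strain and age for 2 pairs of near-identical genes. Ndufs5 averaged 0.839 CPM in NZB/W-F1 at 3 months and 27.5 in C57BL/6, and its copy BC002163 22.7 and 1.11.

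At 6 months the comparison set nephritic NZB/W-F1 mice against controls of the same age. By camera at its preset correlation, lists of myelin and of the mitochondrial genome were lower in NZB/W-F1, and those of interferon-stimulated, immediate early and glucocorticoid-induced genes were higher. None of the 8 lists called by camera held with an estimated correlation (adjusted p with an estimated correlation from 0.637 to 0.749). All 15 myelin genes lay below 0, with a median of -0.48 and a camera adjusted p of 2.91e-05, and 6 were lower over all genes and 13 adjusted over the list alone. Opalin, a protein of mature oligodendrocytes, was lower (-1.01 ± 0.24) (19.5 ± 8.24 CPM, n = 5, against 36.6 ± 3.96, n = 5), Mal (-0.58 ± 0.16) and Cnp (-0.53 ± 0.15). All 7 mitochondrially encoded genes lay below 0 as well, with a median of -0.56, a camera adjusted p of 2.91e-05 and 6 lower both over all genes and adjusted over the list alone. Among them mt-Nd1, a subunit of complex I, was at 3995 ± 618.2 CPM against 6846 ± 979.2, a log2 fold change of -0.78 ± 0.11 (limma adjusted p = 2.91e-05). Of 13 listed genes of the mitochondrial genome only 7 were in the table. The score of this list was already lower at 3 months, without overlap, though camera did not call it there. It was -0.712 ± 0.126 in NZB/W-F1 and -0.105 ± 0.234 in C57BL/6 (exact two-sided permutation p = 0.0159, and 0.245 after adjustment over the lists). At 6 months it was -0.504 ± 0.846 and 1.178 ± 0.541, so that the larger gap came with a rise in C57BL/6. Whether reads of this list were assigned to other genes in NZB/W-F1 was not tested.

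The interferon-stimulated genes, with a median below 0 at 3 months, had 29 of 30 above 0 at 6 months, with a median of 0.58 and a camera adjusted p of 7.89e-05. Over all genes 5 were higher, and 5 adjusted over the list alone. These were Irf7 by 1.10 ± 0.36 and Irf9 by 0.73 ± 0.17, transcription factors of the interferon response, Trim30a by 0.99 ± 0.28, Oas2 by 0.60 ± 0.16 and Dhx58 by 0.58 ± 0.16. Without library 10 of the 6-month NZB/W-F1 group the median was 0.23 and the list kept its call. Per library, however, the scores of this list overlapped between the strains, at 0.80 ± 1.25 in NZB/W-F1 and -0.18 ± 0.39 in C57BL/6. The exact two-sided permutation p was 0.119, and 0.286 after adjustment over the lists. At 3 months it was 0.0476, and 0.245 after adjustment, so that animals did not separate by strain at either age. Of 14 immediate early genes 6 were higher, and 8 adjusted over the list alone, with a median of 0.45 and a camera adjusted p of 0.00136. Examples were Egr2 by 1.22 ± 0.27, Fosb by 0.93 ± 0.12 and Arc by 0.70 ± 0.23. Of 13 glucocorticoid response genes 5 were higher, and 5 adjusted over the list alone, with a median of 0.34 and a camera adjusted p of 0.00817. They were Plin4 by 1.54 ± 0.38, Hif3a by 1.04 ± 0.27, Zbtb16 by 1.01 ± 0.22, Pdk4 by 0.71 ± 0.16 and the clock gene Per1 by 0.43 ± 0.09.

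Among immune genes, the MHC class II gene H2-Ab1 was higher by 1.17 ± 0.33, C4a by 1.21 ± 0.13 and Tnfsf13b, the B cell survival factor BAFF, by 0.78 ± 0.13. For H2 genes, variants against the C57BL/6 reference were not tested at this age either. Fcrls (-2.65 ± 0.16) and Pycard (-0.91 ± 0.13) were again lower. The list of border-associated macrophages and monocytes had 2 of 6 higher, Ly6c2 by 1.54 ± 0.15 and Lyve1 by 0.70 ± 0.15, and the same number adjusted over the list alone, with a median of 0.41 and a camera adjusted p of 0.0309. It lost its call without library 10 of the 6-month NZB/W-F1 group (adjusted p = 0.0678) and with the length trend as a covariate (adjusted p = 0.0595). Of 13 GABAergic interneuron genes 3 were lower, and 3 adjusted over the list alone, with a median of -0.15 and a camera adjusted p of 0.0428. That call was lost without library 10, 11 or 14 of NZB/W-F1 or 32 or 33 of C57BL/6 (median from -0.18 to -0.11, highest adjusted p = 0.105). The neuropeptides Sst (-0.89 ± 0.18) and Npy (-0.88 ± 0.15) were lower, as was Gad1 (-0.28 ± 0.06). Markers of the thalamus, which borders the hippocampus, had a median of 0.99 over 9 genes, all above 0, with 1 called, Prkcd, and 7 adjusted over the list alone, and a camera adjusted p of 0.00817. Their scores were 1.84 and 3.19 in libraries 10 and 11 of the 6-month NZB/W-F1 group and at most -0.10 in the other 3, and without library 11 the list lost its call (median 0.50, adjusted p = 0.0607). The myelin scores were lowest in libraries 14 and 12 of the same group, at -2.45 and -1.39.

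The adjusted p with an estimated correlation was 0.637 for mitochondrial, glucocorticoid, macrophage and GABAergic genes, 0.666 for myelin and immediate early genes and 0.749 for interferon-stimulated and thalamic genes. Over all genes limma called 1031 higher and 1082 lower in NZB/W-F1 at 6 months. Of the 31 genes named here, 29 kept their call without each library, and the other 2 were H2-Ab1, lost without library 10 of NZB/W-F1 or 33 of C57BL/6 (highest adjusted p = 0.0611), and Sox11 (0.37 ± 0.10), lost without library 11 of NZB/W-F1 or 31 or 32 of C57BL/6 (highest adjusted p = 0.0578). Microglial Olfml3 was lower (-0.73 ± 0.07), Gpnmb (-0.78 ± 0.13) and Lpl higher by 1.11 ± 0.15. The progenitor list as a whole was not called (median 0.03, camera adjusted p = 0.578), and of its members Pcna (-0.42 ± 0.07) and Mcm2 (-0.51 ± 0.11) were lower. The proapoptotic p53 target Bbc3 was lower (-0.57 ± 0.13) and the p53 target Aen higher by 0.30 ± 0.07. Myoc was lower (-2.55 ± 0.30), Hba-a2 (-2.62 ± 0.22), and H2-T22 (-0.98 ± 0.11), and H2-DMa was higher by 0.58 ± 0.10. The near-identical copies of Hba-a2 and H2-T22 went the other way. Hba-a1 was higher by 1.92 (limma adjusted p = 0.0307) and H2-T10 by 1.24 (limma adjusted p = 4.66e-06). Of the pancreatic enzymes, Cela2a was at 10.5 ± 1.22 CPM in NZB/W-F1 and at 0 in every C57BL/6 library of 6 months, at least 45.3-fold higher at a floor of 0.231 CPM.

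Of 2697 genes called between strains at either age, 93.4% had the same sign at both ages, which share no library, against 70.5% of all 15298 genes. The log2 fold changes had a Pearson r of 0.838 across genes, which are not independent replicates, and 0.771 without pseudogenes. Of the 2697 genes, 569 were higher at both, where 61.6 would be expected for independent lists, and 536 were lower at both, where 54.9 would be expected. A single gene was called in opposite directions. In all, 584 were called at 3 months alone and 1007 at 6 months alone, but limma called the change in strain difference for 0 of the 15298 genes, with 990 at an unadjusted p under 0.05, 0 called by edgeR and 8 by DESeq2. By chance, 765 genes would be expected under that unadjusted p.

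**Figure D2:**
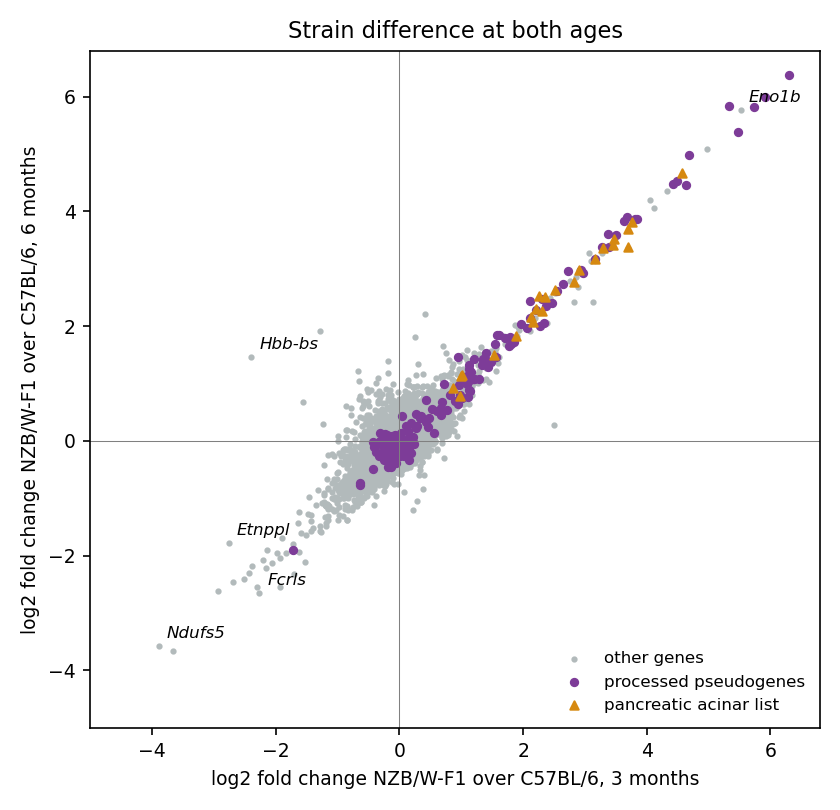
Log2 fold change of NZB/W-F1 over C57BL/6 at 3 months (horizontal axis) and at 6 months (vertical axis), on the log2(CPM + 1) scale, 1 point per gene. Pearson r across genes was 0.838, Eno1b lay at 5.52 and 5.76, and Ndufs5 at -3.90 and -3.58.

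Within NZB/W-F1, the step from 3 to 6 months set the nephritic stage against the stage before it. C4b, a complement gene that astrocytes and oligodendrocytes raise in inflammation, rose from 33.8 ± 6.65 CPM (n = 4) to 74.2 ± 17.3 (n = 5), 2.15-fold (limma adjusted p = 0.00697). It is ENSMUSG00000073418.4 on chromosome 17, 34728380 to 34743882. Ctss, a lysosomal protease of microglia, rose from 73.0 ± 10.2 to 110.3 ± 15.6 CPM (log2 fold change 0.59 ± 0.11, limma adjusted p = 0.0335). Gpr17 (ENSMUSG00000052229.5, chromosome 18, 31942997 to 31949636) fell from 90.7 ± 7.96 to 46.2 ± 8.95 CPM (-0.97 ± 0.14, limma adjusted p = 0.00697). Frem3, a gene of the extracellular matrix, rose from 2.52 ± 0.334 to 7.11 ± 1.40 CPM (1.19 ± 0.13), Spag6 by 1.03 ± 0.11, the cold-inducible RNA-binding protein Rbm3 by 0.92 ± 0.17 and the globin Hbb-bt by 2.25 ± 0.43. Hsp90b1, an endoplasmic reticulum chaperone, fell by 0.46 ± 0.08 on the log2 scale, as did Plod1 (-0.44 ± 0.08), Rbm28 (-0.43 ± 0.07) and Lman2l (-0.43 ± 0.08). In all, limma called 12 genes higher and 8 lower at 6 months, a count that other tools and settings moved several-fold, as given with the processing below.

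The interferon response rose in NZB/W-F1 with age as a list. All 30 interferon-stimulated genes lay above 0 at a median of 0.72, and camera gave an adjusted p of 4.86e-24. Over all genes limma called 0 of the 30, against 25 adjusted over the list alone, with 26 at an unadjusted p under 0.05, 0 called by edgeR and 11 by DESeq2. Ifit3 went from 3.28 to 16.5 ± 14.2 CPM (1.67 ± 0.41), Irf7 from 2.18 to 7.97 CPM (1.18 ± 0.38) and Ifit1 from 1.96 to 8.69 ± 9.91 CPM (1.24 ± 0.44). The list lost its call when the correlation between its genes was estimated (adjusted p = 0.127 with an estimated correlation). The animals of 6 months differed widely, with list scores of 2.67 in library 10, 1.43 in library 14, 0.22 and 0.18 in libraries 11 and 12 and -0.47 in library 13, against -0.78 to -0.52 in all 4 libraries of 3 months. Every library of 6 months thus lay above every library of 3 months, which gave an exact two-sided permutation p of 0.0159, the smallest that 4 against 5 allow, and 0.0816 after adjustment over the lists.

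MHC class I presentation rose as a list too. All 17 genes lay above 0 at a median of 0.60 (camera adjusted p = 9.37e-12), 10 of them called when adjusted over the list alone and 0 by limma over all genes, with 12 at an unadjusted p under 0.05, 0 called by edgeR and 6 by DESeq2. H2-D1 went from 39 to 80 CPM (0.90 ± 0.24) and B2m from 61.8 to 103.7 (0.69 ± 0.17). Without library 10 of 6 months the median was 0.34 (adjusted p = 3.89e-08). The adjusted p with an estimated correlation was 0.145. Of 16 complement genes 1, C4b, rose over all genes and 5 adjusted over the list alone, the others being C3ar1 (0.76 ± 0.19), Itgb2, C1qc and C1qa, with a list median of 0.27 (camera adjusted p = 0.000121, and adjusted p = 0.18 with an estimated correlation). Of 18 activated microglial genes 1, Ctss, rose over all genes and 5 adjusted over the list alone, including Cybb (0.96 ± 0.27) and Trem2 (0.40 ± 0.13), with a median of 0.18 (camera adjusted p = 3.75e-05, and adjusted p = 0.196 with an estimated correlation). MHC class II genes had a median of 0.50 and a camera adjusted p of 0.0104, which became 0.239 without library 10, where the median was 0.20 (adjusted p = 0.357 with an estimated correlation). The 12 lupus susceptibility genes had a median of 0.24, with Cd48 (0.60 ± 0.13) and Irf5 (0.34 ± 0.11) called when adjusted over the list alone (camera adjusted p = 0.000107, and adjusted p = 0.0587 with an estimated correlation).

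**Figure D3:**
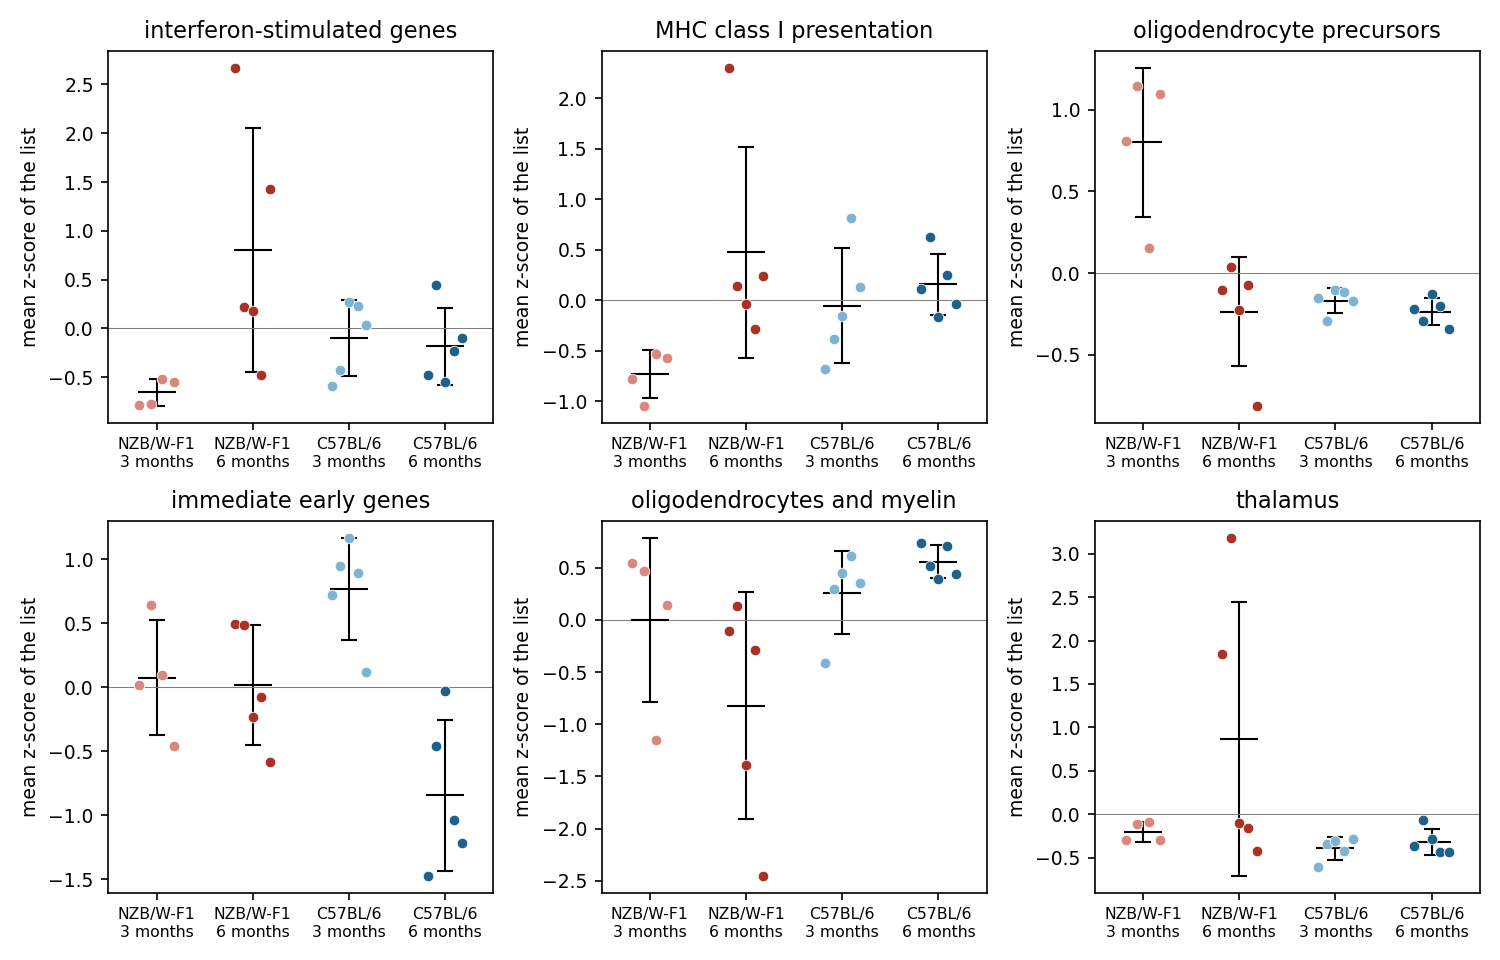
Mean z-score over the genes of a list (vertical axis, SD units) for each library (points), with mean and SD (bars) by strain and age, for 6 of the lists. Interferon-stimulated genes ran from -0.47 to 2.67 in NZB/W-F1 at 6 months and from -0.78 to -0.52 at 3 months.

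Other lists went the other way. All 10 genes of oligodendrocyte precursors lay below 0 at a median of -0.19, with 1 lower over all genes and 4 adjusted over the list alone, namely Gpr17, Enpp6 (-0.68), Olig2 (-0.49) and Neu4 (-0.27). This list had a camera adjusted p of 1.92e-06 and was the one of 19 called in this comparison to keep its call with an estimated correlation (adjusted p = 0.00532). Of 15 myelin genes 6 fell when adjusted over the list alone, such as Ugt8a (-0.82 ± 0.22), with a median of -0.29 (camera adjusted p = 1.64e-05, and adjusted p = 0.332 with an estimated correlation). Without library 14 of 6 months that median was -0.16 (adjusted p = 0.0114). Over all genes limma called 0 of these 15, with 7 at an unadjusted p under 0.05, 0 called by edgeR and 1 by DESeq2. Of 16 genes of the heat shock and unfolded protein response 1 fell over all genes, and 10 fell and 1 rose adjusted over the list alone, with a median of -0.35 (camera adjusted p = 2.41e-11, and adjusted p = 0.127 with an estimated correlation). Calr fell by 0.58 ± 0.12 and Hspa5 by 0.55 ± 0.15 on the log2 scale under that narrower adjustment. Blood cell genes rose, 1 of 5 over all genes and 4 adjusted over the list alone, with a median of 2.25 (camera adjusted p = 1.54e-08, and adjusted p = 0.0587 with an estimated correlation). Hbb-bs ran from 0.0423 to 24.5 CPM in libraries of 3 months and from 17.5 to 123.7 in those of 6 months. Thalamic markers lay above 0 in all 9 genes at a median of 0.72 (camera adjusted p = 1.64e-05, and adjusted p = 0.271 with an estimated correlation), and at 0.32 without library 11 and 0.53 without library 10 of 6 months. Their list score was 0.87 ± 1.58 at 6 months and -0.20 ± 0.12 at 3 months (exact two-sided permutation p = 0.333). Camera also called ribosomal proteins (median 0.18), nuclear-encoded oxidative phosphorylation (0.10), cytokines (0.17) and homeostatic microglia (0.13) higher, and meninges (-0.59), GABAergic interneurons (-0.13), excitatory synapse (-0.11) and neuroblasts (-0.11) lower. Their adjusted p with an estimated correlation was 0.593, 0.621, 0.183 and 0.196 for the higher ones and 0.31, 0.18, 0.646 and 0.0587 for the lower ones, in the same order. The call was lost for homeostatic microglia without library 8 or 9 of 3 months or 12 or 14 of 6 months (median from 0.11 to 0.13, highest adjusted p = 0.12), for excitatory synapse without 5 or 8 of 3 months or 11 of 6 months (median -0.06, -0.08 and -0.05, highest adjusted p = 0.337), and for GABAergic interneurons without 8 of 3 months or 10 of 6 months (median -0.11 and -0.10, highest adjusted p = 0.0869). Without library 10 the medians were 0.11 for cytokines and 0.18 for oxidative phosphorylation, without library 9 they were -0.38 for meninges and -0.17 for neuroblasts, and without library 5 it was -0.22 for GABAergic interneurons. Of the 19 lists called, 15 kept their call without each library.

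In NZB/W-F1 the length trend had a rho of 0.245 to 0.475 in the libraries of 3 months and of -0.17, -0.17 and -0.05 in libraries 11, 13 and 14 of 6 months, against 0.46 and 0.28 in libraries 10 and 12. With this trend as a covariate, chosen after the data were seen, the median with age turned to -0.02 for oxidative phosphorylation and to 0.04 for excitatory synapse. It fell to 0.01 for ribosomal proteins, for which the direction given by camera turned (adjusted p = 0.925). Activated microglia (median 0.11, adjusted p = 0.0609) and MHC class II presentation (0.47, 0.165) lost their call with it. With Hbb-bs as a covariate, also chosen after the data were seen, 8 of the 19 lists lost their call. The medians were then 0.01 for blood cells, 0.20 for complement, 0.11 for MHC class II presentation, -0.02 for cytokines, 0.08 for homeostatic microglia, 0.14 for lupus susceptibility genes, -0.09 for excitatory synapse and -0.08 for GABAergic interneurons. Hbb-bs is itself a member of the blood cell list, so the loss of that call was largely fixed by the choice of covariate.

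**Figure D4:**
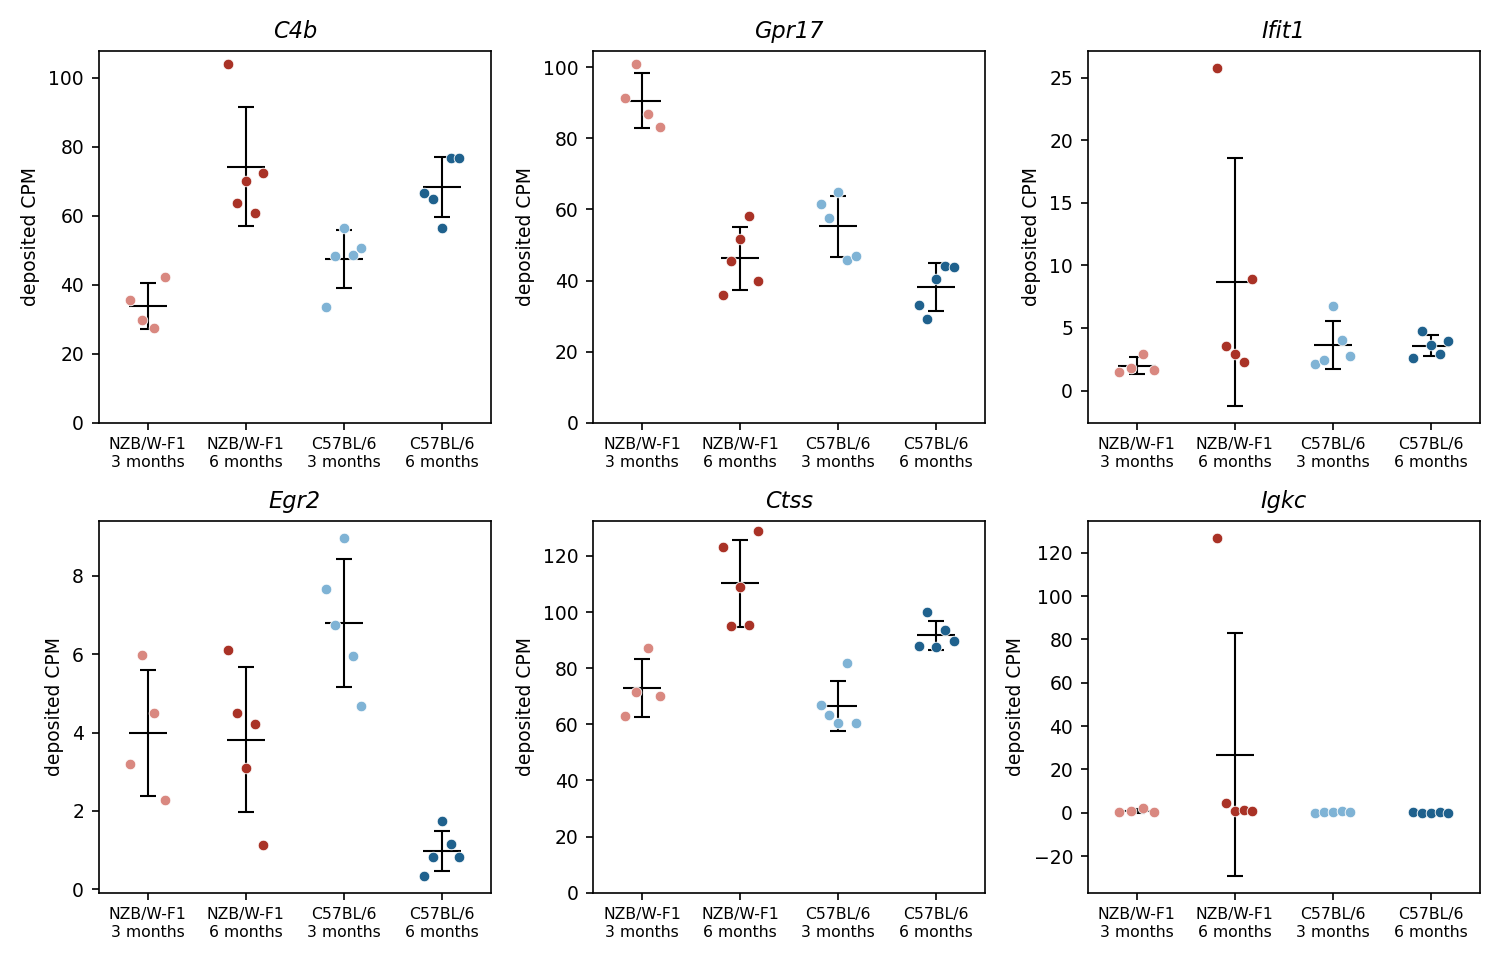
CPM of each library (points) with mean and SD (bars) by strain and age for C4b, Gpr17, Ifit1, Egr2, Ctss and Igkc. C4b averaged 33.8 CPM in NZB/W-F1 at 3 months and 74.2 at 6 months, and Gpr17 90.7 and 46.2.

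Of the 11 genes named for age in NZB/W-F1, Frem3, C4b, Spag6 and Gpr17 kept their call without each of the 19 libraries. For the other 7 the highest adjusted p with a library left out was 0.13 for Hsp90b1, 0.138 for Hbb-bt, 0.14 for Rbm28, 0.161 for Ctss, 0.2 for Rbm3 and 0.209 for Plod1 and Lman2l. The count of 20 genes fell to 6 without library 7 of NZB/W-F1 at 3 months, to 7 without libraries 5, 9 or 10, to 10 without library 14 and to 11 without library 11, or libraries 34 or 35 of C57BL/6, and was 49 without library 39 of C57BL/6.

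Within C57BL/6, the same step in age gave the change without lupus. The immediate early genes fell. Egr2, a transcription factor induced by synaptic activity (ENSMUSG00000037868.15, chromosome 10, 67535475 to 67542188), fell from 6.803 ± 1.636 CPM (n = 5) to 0.979 ± 0.515 (n = 5), a log2 fold change of -1.99 ± 0.27 (limma adjusted p = 0.00118). Fos fell from 22.3 ± 5.20 to 8.52 ± 3.81 CPM, Fosb from 14.01 ± 1.82 to 5.77 ± 0.461, Egr1 from 178.7 ± 19.1 to 91.4 ± 15.7, and Npas4 from 11.9 ± 2.53 to 4.51 ± 2.33. Of the 14 genes of the list 7 fell over all genes and 13 adjusted over the list alone, with a median of -0.71 (camera adjusted p = 8.8e-15, and adjusted p = 0.123 with an estimated correlation). The list score was 0.77 ± 0.40 at 3 months and -0.84 ± 0.59 at 6 months, with an exact two-sided permutation p of 0.00794, the smallest possible for 5 against 5, and 0.0952 after adjustment over the lists.

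Mitochondrially encoded genes rose with age in C57BL/6, 1 of 7 over all genes and 7 adjusted over the list alone, with a median of 0.40 (camera adjusted p = 1.67e-05, and adjusted p = 0.534 with an estimated correlation). Homeostatic microglial genes rose, 3 of 15 over all genes and 4 adjusted over the list alone, with P2ry12 by 0.47 ± 0.11, Gpr34 by 0.44 ± 0.11 and P2ry13 by 0.41 ± 0.10 (camera adjusted p = 0.0474, and adjusted p = 0.583 with an estimated correlation). That list had a median of 0.16 and lost its call without any of 10 libraries, which were 37 to 40 of 3 months, 31, 33, 34 and 35 of 6 months, and 5 and 11 of NZB/W-F1 (highest adjusted p = 0.116, and median 0.09, 0.10 and 0.07 without 39, 40 and 33). Ctss rose by 0.47 ± 0.10. Of 14 neuroblast genes, 1 fell over all genes, Dpysl3, and 4 adjusted over the list alone (median -0.11, camera adjusted p = 0.0474, and adjusted p = 0.238 with an estimated correlation). Its call was lost without any of 8 libraries, which were 36 to 39 of 3 months, 31, 33 and 35 of 6 months, and 11 of NZB/W-F1 (median from -0.14 to -0.07, highest adjusted p = 0.14). Choroid plexus genes had a median of -0.83, with all 16 below 0, and the list lost its call without library 39 or 40 of the 3-month group, which held 7649 and 5116 CPM of Ttr (camera adjusted p = 0.00765, adjusted p = 0.993 with an estimated correlation, and 0.304 as the highest with 1 library left out, with medians of -0.35 without 39 and -0.42 without 40), and without both, a choice made after the data were seen, its median turned to 0.39. Meningeal genes had a median of -0.59, with 2 lower adjusted over the list alone (camera adjusted p = 0.0177, and adjusted p = 0.993 with an estimated correlation), and lost their call without library 39, 40 or 34 (median -0.46, -0.36 and -0.44, highest adjusted p = 0.165). Heat shock genes had a median of -0.12 and lost their call without library 39, 40 or 35 (median -0.03, -0.08 and -0.09, highest adjusted p = 0.336), and the median was -0.19 without library 37 and turned to 0.06 without both 39 and 40. Without both, the calls of homeostatic microglia (median 0.03), neuroblasts (-0.14) and meninges (-0.13) were lost too, and those of homeostatic microglia and neuroblasts were lost with the length trend as a covariate (adjusted p = 0.0548 and 0.101). Spag6 rose by 1.06 ± 0.11, Rbm3 by 0.88 ± 0.16, Ftx by 0.86 ± 0.20, Abca8a by 0.79 ± 0.16, Zfp40 by 0.79 ± 0.15 and Ccng1 by 0.26 ± 0.06.

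In all, limma called 417 genes higher and 130 lower at 6 months in C57BL/6. Libraries 39 and 40 of 3 months and 32 of 6 months stood apart in the trend of expression with transcript length (rho of -0.68, -0.47 and -0.51, against -0.17 to 0.48 in the other 16). Without libraries 39 and 40, a choice made after the data were seen, 981 genes were higher and 1117 lower, with 430 of the 547 genes among them, and without 1 library the count ran from 220 (library 32) to 982 (library 39), with 225 without library 40, 284 without library 33 and 352 without library 34. Of the 15 genes named for this comparison 9 kept their call without each library, and the highest adjusted p was 0.101 for Gpr34, 0.0842 for Ccng1, 0.0767 for Ftx, 0.0753 for P2ry12, 0.0569 for mt-Nd1 and 0.0533 for Ctss.

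The interaction asked whether the change from 3 to 6 months differed between the strains. No single gene was called by limma (0 of 15298, smallest adjusted p 0.26), with 990 at an unadjusted p under 0.05, 0 called by edgeR and 8 by DESeq2. Under that unadjusted p 765 genes would be expected by chance. For C4b the difference between the changes was 0.58 ± 0.22 (limma adjusted p = 0.67), as C57BL/6 went from 47.5 to 68.3 CPM, and for Gpr17 it was -0.45 (adjusted p = 0.739). Camera called 17 lists, of which 0 kept the call with an estimated correlation (17 at the preset correlation, 2 with fry). Interferon-stimulated genes gained more in NZB/W-F1, with all 30 above 0 and a median difference of 0.86 (camera adjusted p = 4.29e-18, and adjusted p = 0.3 with an estimated correlation), 14 adjusted over the list alone. In C57BL/6 their median change was -0.07 (camera adjusted p = 0.713). The immediate early genes had a median change of 0.04 in NZB/W-F1 (camera adjusted p = 0.493) and fell in C57BL/6, a median difference of 0.76 with 10 of 14 called when adjusted over the list alone (camera adjusted p = 1.87e-14, and adjusted p = 0.0714 with an estimated correlation). For Egr2 the difference was 1.89 ± 0.40 and for Egr1 1.05 ± 0.20. Oligodendrocyte precursors fell more in NZB/W-F1, by a median difference of -0.27 (camera adjusted p = 0.000844, and adjusted p = 0.0714 with an estimated correlation). MHC class I presentation (0.56) and complement (0.32) gained more and myelin (-0.35) less in NZB/W-F1, with adjusted p = 0.413, 0.375 and 0.467 with an estimated correlation. The median for MHC class I presentation was 0.34 without library 10 of NZB/W-F1, and that for myelin -0.54 without library 8. Of the 17 lists, 10 kept their call without each library. Without libraries 39 and 40 of C57BL/6 together, a choice made after the data were seen, complement lost its call (median 0.14, adjusted p = 0.202).

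Genes fixed by name for their interest in neuropsychiatric lupus included Il18, Aif1, Dcx, Gfap and Ttr, none of which passed in any of the 5 comparisons. The log2 fold change between strains of the inflammasome cytokine Il18 was -0.02 ± 0.10 at 3 months and -0.26 ± 0.10 at 6 months (limma adjusted p = 0.909 and 0.0823). The microglial marker Aif1, which encodes Iba1, differed by 0.22 ± 0.19 and 0.32 ± 0.18 (limma adjusted p = 0.495 and 0.298), and changed with age in NZB/W-F1 by 0.28 ± 0.19 (0.768). Dcx, the marker of immature neurons, stood at 16.8 ± 1.25, 15.4 ± 2.04, 18.1 ± 5.91 and 16.3 ± 1.20 CPM in NZB/W-F1 of 3 and 6 months and C57BL/6 of 3 and 6 months. Its log2 fold changes lay between -0.12 and -0.05, with limma adjusted p up to 0.911. Gfap, the astrocyte filament, stood between 463.0 and 502.8 CPM in all 4 groups. For C4b the log2 fold change between strains was -0.48 ± 0.16 at 3 months (limma adjusted p = 0.0621) and 0.10 ± 0.15 at 6 months (0.757). For Ttr, made by the choroid plexus, it was -1.23 ± 1.53 at 3 months and 0.29 ± 1.45 at 6 months (limma adjusted p = 0.644 and 0.935). Il6, Il1b, Tnf and Ifi202b were not analysed here.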

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

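Tests of the shift from parent genes, of depth and of sample numbers for pseudogenes, and of library 10 for interferon-stimulated genes, were chosen only after the result was seen, as were the pancreatic gene list and the covariates and left-out libraries named as added.

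Processed pseudogenes, intronless copies of other genes, were higher in every NZB/W-F1 library, summing to 1093 ± 64.7 CPM (n = 9) against 332.5 ± 21.6 in C57BL/6 (n = 10), with 61 of 186 over 2-fold higher at both ages and 1 lower. Gm13340, an unprocessed pseudogene on chromosome 2 and outside that sum, stood at 438.2 and 495.8 CPM in NZB/W-F1 of 3 and 6 months. In C57BL/6 it stood at 1.094 and 1.505 CPM. Across 164 processed pseudogenes the gain had a Spearman rho of -0.086 with the level of the parent (permutation p = 0.271). This gave no sign of reads spilling over in proportion to the parent's level. It cannot exclude such spillover, since copies with too few reads to enter the table were not seen. The tables argue against depth, as the shallowest NZB/W-F1 library (16.47M reads) held 3.31 times the processed pseudogene CPM of a deeper C57BL/6 library (18.41M). Reads moved from parent to copy may explain part of it, since the parents of the raised copies had a median log2 fold change of -0.26 against -0.10 for the others, a difference of -0.155 with a permutation p of 1e-05, the smallest the permutations can give. Copies that share a parent were not merged in these permutations, so that p can be too small. Separate handling of the strains cannot be told apart from strain for these genes, because 0 NZB/W-F1 sample numbers lie inside the C57BL/6 range. Strain variants against the C57BL/6 reference, which the design's strains would bring, stay open and untested.

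Pancreatic enzyme transcripts stood in every NZB/W-F1 library, where 23 acinar genes summed to 174 ± 32.5 CPM (0.0174% of reads) against 5.48 ± 1.3 in C57BL/6. A trace of pancreatic RNA is a candidate source, from a list of 35 acinar genes, of which 23 were in the table and 4 had been seen. The 19 genes not looked at before had a median log2 fold change of 2.25 at 3 months and 2.31 at 6 months. Their median log2 ratio was at least 4.13 and 4.11 with the 12 genes at 0 in C57BL/6 set to the floor. These values are no independent test of that source. Every gene in the deposited table reached at least 0.987 CPM in 4 libraries. The 12 of 23 acinar genes at 0 in every C57BL/6 library could therefore be in it only through NZB/W-F1. The tables argue against pancreas carried over at single dissections, as the sum varied by 18.7% between the 9 libraries. They also argue against a variant at 1 locus that acts only on genes near it, as the genes lie on 10 chromosomes. A variant at 1 locus that acts on genes elsewhere was not tested. The 3 most abundant were Ctrb1 at 23.3, Pnlip at 16.4 and Cela1 at 14.2 CPM at 3 months, and the table held 0 of 6 islet, 0 of 14 liver, 1 of 10 kidney and 4 of 10 muscle genes listed beside them. Where the RNA entered, and a true strain difference in hippocampal expression, stay open.

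Interferon-stimulated genes rose from 3 to 6 months in NZB/W-F1 as a list, with a median log2 fold change of 0.717. Over all genes limma and edgeR called 0 of the 30 and DESeq2 11, with 26 at an unadjusted p under 0.05. The camera call of this list was lost when the correlation between its genes was estimated. The tables argue against 1 library as the whole cause, as the median was 0.513 without library 10, and against the transcript-length trend, a sign of RNA quality, as it was 0.758 with that trend as a covariate. Blood left in the tissue cannot be told apart from the rise, since the median was 0.452 with Hbb-bs as a covariate and Hbb-bs itself was higher in nearly all 6-month libraries. In C57BL/6 of the same ages the median was -0.074, and the median difference between the strains' changes was 0.855, with adjusted p = 0.3 with an estimated correlation. The nephritic stage, and a change with age of NZB/W-F1 alone, come together in this design and stay open as biological explanations.

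Among 100 splits of the same libraries, counts of genes as large as the real one were rare. Between strains they came in 1 split, the real one, at 3 months (1690, highest other 1521) and at 6 months (2113, highest other 1). With age they came in 2 splits in NZB/W-F1 (20, highest other 27) and 3 in C57BL/6 (547, highest others 1831 and 1338), the real one included. The agreement of the strain differences was as large in 1 split, the real one (0.838, highest other 0.732). A random split thus rarely gave such values, but the splits do not exclude another structure of the libraries as a source of the age counts. The split with 1831 genes put libraries 39 and 40 of 3 months with 31, 32 and 33 of 6 months, which points to a structure of the C57BL/6 libraries other than age, and that with 1521 put libraries 37 to 40 of C57BL/6 together, nearly the real split. Chance was not excluded for the counts of lists: 8 between strains at 3 months (50 splits as large, highest other 14), 8 at 6 months (69, highest other 23), 19 with age in NZB/W-F1 (14, highest other 25), 7 with age in C57BL/6 (39, highest other 14) and 17 for the interaction (13, highest other 21). For the interaction count of genes, 0 by limma (unadjusted p under 0.05 for 990 with 765 expected by chance, edgeR 0, DESeq2 8), the splits decide nothing, as all 100 reach 0 whatever the data, with a highest other of 9.

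Single libraries far from the rest of their group were looked for in list scores (5 of 144 groups, 7.2 expected), named genes (17 of 268, 13.4 expected) and library sums (1 of 20, 1 expected), as chance gives about 1 in 20. Library 10 of NZB/W-F1 at 6 months had the highest scores of MHC class I presentation, 2.305 (next 0.246), and MHC class II presentation, 2.308 (next 0.34), with 19.5 CPM of H2-T23, 13.5 of H2-Ab1 and 104 of C4b, and the lowest Rpl29, 8.97. Library 14 of that group had the lowest Plod1, 24.5 CPM, and Abca8a, 11.4, and library 12 the highest Hba-a2, 0.1 CPM, with 0 in the others. At 3 months, library 9 of NZB/W-F1 had the highest Pnlip, 22.9 CPM, Cela2a, 16.7, and Ttr, 2940, library 7 the highest Hba-a2, 0.0511, and library 5 the lowest neocortex score, -0.304. In C57BL/6 of 3 months library 39 had the highest Ndufs5, 45.2 CPM, and library 36 the highest Ndufs1, 167. At 6 months library 33 had the highest astrocyte score, 0.374, and Egr1, 118 CPM. Library 35 had the lowest heat shock score, -0.732, the highest Gpr34, 23 CPM, and the highest Cpa1, 0.117 CPM, which are few reads. Library 31 had the highest Ttr, 1460 CPM, and the lowest acinar sum, 3.95.

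The change with age differed between the strains for 17 lists by the interaction term in camera, each given as the median difference in log2 fold change. It was above 0 for blood cells (2.242), interferon-stimulated genes (0.855), immediate early genes (0.76), thalamus (0.756), choroid plexus (0.583), MHC class I presentation (0.562), complement (0.32), activated microglia (0.173), ribosomal proteins (0.17) and reactive astrocytes (0.109). It was below 0 for myelin (-0.354), mitochondrially encoded genes (-0.332), oligodendrocyte precursors (-0.267), heat shock (-0.203), dentate gyrus (-0.194), CA1 (-0.187) and GABAergic interneurons (-0.168). All 17 calls were lost when the correlation was estimated, with adjusted p from 0.0714 for immediate early genes and oligodendrocyte precursors to 0.693 for ribosomal proteins with an estimated correlation. At the preset correlation 7 calls were lost without some library. Choroid plexus lost its call without library 7, 8 or 10 of NZB/W-F1 or 39, 40, 32 or 33 of C57BL/6, with medians from 0.139 (without 39) to 1.234 (without 9 of NZB/W-F1) over all 19 libraries left out in turn. Reactive astrocytes lost it without 8 or 10 of NZB/W-F1 or 37 or 39 of C57BL/6 (lowest 0.018, without 10), dentate gyrus without 5 of NZB/W-F1 or 39 or 40 of C57BL/6 (nearest to 0 at -0.125, without 39) and CA1 without 8 of NZB/W-F1 or 36 or 39 of C57BL/6 (-0.129, without 8). Activated microglia (0.037) and ribosomal proteins (-0.014) lost it without library 39 and GABAergic interneurons (-0.141) without library 10. The median of the dentate gyrus was -0.361 without 36, -0.328 without 32, -0.304 without 9 and -0.298 without 10, that of the choroid plexus 0.876 without 36 and 0.9 without 31, that of reactive astrocytes 0.069 without 33, and that of ribosomal proteins 0.11 without 31. Other medians that moved over 1.5-fold were 0.374 for thalamus without library 11, 0.339 for MHC class I presentation without library 10 and -0.536 for myelin without library 8. Without libraries 39 and 40 of C57BL/6 together the medians turned to -0.755 for choroid plexus, -0.069 for activated microglia and -0.12 for ribosomal proteins, the last called in that direction (adjusted p = 0.00278). Complement (0.144), reactive astrocytes (0.077), dentate gyrus (-0.023) and CA1 (-0.174) then lost their call, and with the length trend as a covariate reactive astrocytes (0.117) and choroid plexus (0.449) did.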

How the results depend on the processing

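Leaving out libraries 39 and 40 of C57BL/6 at 3 months, the covariates and leaving out pseudogenes were chosen after the data were seen; the other alternatives were fixed before. Of 209 counts and agreement values with 1 library left out, 187 stayed the same, and of 104 under other alternatives fixed beforehand 80 did. A count was the same within 1.5 times of the main value. Agreement was the same if it moved by less than 0.0624, its SE from leaving out each library. Counts of genes ran from 1167 to 1975 and from 1671 to 2867 for strain at 3 and 6 months, from 6 to 49 and from 220 to 982 for age in NZB/W-F1 and C57BL/6, and from 0 to 2 for the interaction (limma, 990 at an unadjusted p under 0.05 in all libraries with 765 expected by chance, edgeR 0, DESeq2 8). Agreement ran from 0.801 to 0.859, and counts of lists from 2 to 9, 7 to 11, 17 to 21, 3 to 8 and 11 to 20 in the order of the contrasts. Fits on the compared groups alone, which hold fewer samples, gave 959 genes for strain at 3 months, 6 for age in NZB/W-F1 and 108 for age in C57BL/6. Array weights gave 2692, 3486, 206 and 2449 for strain at 3 and 6 months and age in NZB/W-F1 and C57BL/6, and a minimum log2 fold change of 0.5, which can only lower a count, gave 872, 974, 13 and 111. DESeq2 gave 173 for age in NZB/W-F1, 897 in C57BL/6 and 8 for the interaction. Without libraries 39 and 40 the counts were 3412 for strain at 6 months, 93 for age in NZB/W-F1 (all 20 genes kept) and 2098 in C57BL/6, and with the length trend 3404, 157 and 3007. Without pseudogenes and pancreatic genes agreement was 0.743. With an estimated correlation 0, 0, 1, 0 and 0 lists passed camera in the order of the contrasts, against 8, 8, 19, 7 and 17, and with fry 3, 6, 4 and 2 for strain at 3 months, age in NZB/W-F1 and C57BL/6 and the interaction. A filter of 5 CPM gave 3 lists for age in C57BL/6, with fewer genes tested, and strain at 3 months had 5 lists without libraries 39 and 40 and 5 with the length trend. Reversed medians without these libraries were 0.023 for oxidative phosphorylation (strain at 3 months), 0.39 for choroid plexus and 0.061 for heat shock (age in C57BL/6), and -0.069, -0.755 and -0.12 for activated microglia, choroid plexus and ribosomal proteins (interaction), the last with -0.014 to 0.234 when 1 library was left out (lowest without library 39). With the length trend they were 0.038 for excitatory synapse and -0.016 for oxidative phosphorylation (age in NZB/W-F1), and for ribosomal proteins the direction given by camera turned while the median, 0.014, kept its sign. Conversely, the median alone changed sign for ribosomal proteins without libraries 39 and 40 (strain at 3 months, 0.001) and for cytokines with Hbb-bs as a covariate or a filter of 5 CPM (age in NZB/W-F1, -0.02 and -0.031). Apart from the fits with fewer samples or genes, the cause was not tested. Of 87 called results of named genes, none reversed and 67 held without each library, with 2 other pseudocounts and with median-of-ratios and quantile scaling, the settings run for single genes. Depth limits genes near the floors of 0.153 to 0.231 CPM.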

Other observations

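The genes of this part were chosen after their values were seen. Gabra2, a subunit of the GABA-A receptor, stood at 327 and 306.9 CPM in NZB/W-F1 of 3 and 6 months and at 87.4 and 85.5 in C57BL/6 (log2 fold change 1.91 and 1.83, limma adjusted p = 2.3e-11 and 1.6e-11). Wdfy1, an endosomal adaptor of Toll-like receptor signalling, was higher in NZB/W-F1 too, by 2.11 and 1.92. Of the clock genes, Per3 was higher in NZB/W-F1 by 1.04 at 3 months and 0.53 at 6 months, and Per2 by 0.40 and 0.48.

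Part of the age change was shared by both strains. Their log2 fold changes from 3 to 6 months had a Pearson r of 0.309 across genes, which are not independent replicates. Of the 20 genes called in NZB/W-F1, 5 were also called higher in C57BL/6, namely Spag6, Rbm3, Zc3hav1, Ctss and Tipin, where 0.33 would be expected for independent lists. A further 3 were called lower in both, Gpr17, Lman2l and Kank1, where 0.07 would be expected, and 0 were called in opposite directions by limma. The interaction had 990 genes at an unadjusted p under 0.05 with 765 expected by chance, 0 called by edgeR and 8 by DESeq2. The other genes called in NZB/W-F1 included Vegfa, the endothelial growth factor, which rose by 0.61 on the log2 scale, Cyp4f15 (0.65), Itih3 (0.63) and the chaperone Hyou1 (-0.37).

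Library 10 of NZB/W-F1 at 6 months also held 126.6 CPM of Igkc, the antibody light chain of plasma cells, and 28.9 of Cd74. Library 33 of C57BL/6 at 6 months held 0.29 CPM of Xist, against 224.3 to 704.6 in the other 18 libraries, which puts its female label in doubt. Without that library limma called 284 genes for age in C57BL/6 and 1744 between strains at 6 months.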
